A study of Caenorhabditis elegans with 21 samples.

How the data were processed

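Whole-worm RNA of C. elegans N2 was sequenced in 21 libraries, 3 in each of 7 groups. Per the labels' protocols, synchronized worms were grown at 20 °C on E. coli OP50 and collected on day 1 of adulthood. Drug groups went onto plates with 200 µM fluphenazine, 200 µM cantharidin, 10 µM or 25 µM bortezomib at L4, the RNAi group onto rpn-6 RNAi plates at L3, and the starved group onto empty plates 15 h before collection. RNA was extracted with Trizol, cleaned on RNeasy columns and made into stranded mRNA libraries with the TruSeq kit. The deposited values are FPKM (fragments per kilobase of transcript, scaled by the mapped fragments) for 1 column per library. CASAVA and Cufflinks are named in the labels without version or role; the aligner, the genome build and the filters were not given in the sources used here, so no coordinates are printed. Bortezomib titles were read as a replicate digit followed by the dose, a reading that gives 3 libraries per dose.

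The table lists 46254 gene IDs, of which 43200 were joined by WormBase ID to names of annotation release 115 and 3054 had no name there. No 2 columns were identical, and the FPKM of a library summed to between 938941 and 1036350. Read totals were not given, so relative depth was estimated from the table. At low values, the ratios between values of 1 gene in 2 libraries fall on steps set by whole fragments; 55.6% to 69.2% of low values lay within 0.03 log2 of the steps and 10.2% to 16.0% within that distance of shifted steps. All 190 comparisons between 2 other libraries gave the same relative depth within 0.1 log2. It ran from 0.943 to 1.499 of control 4. Some zeros stand in abundant genes: pas-5, a proteasome subunit gene, is listed at 0 in 9 libraries and at 225.6 to 478.1 FPKM in the others. In 60 genes with a median above 20 FPKM there were 154 such values, which may be failed estimates of the upstream software; they were kept, and treated as missing in 1 alternative.

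Genes with at least 1 FPKM in at least 3 libraries were kept (17492). Values were analysed as log2(FPKM + 1) in limma 3.58.1 (R 4.3.3) with lmFit and eBayes (trend = TRUE), 1 mean per group, no covariate, all 21 libraries in 1 fit, 14 residual degrees of freedom and 2.01 prior degrees of freedom. A count model was not used because the values are not counts. Tests were two-sided with Benjamini-Hochberg adjustment, and a gene is called at an adjusted p under 0.05. The 8 comparisons were each treatment against control, the 2 bortezomib doses against each other, and 25 µM bortezomib against rpn-6 RNAi; all 15 pairs of treatments were also contrasted. No paired analysis was possible for starvation, fluphenazine, cantharidin and 10 µM bortezomib against control because each shares at most 1 replicate number with the controls.

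The 26 gene lists were fixed as symbol patterns before the data were examined, as were the tests and most alternatives. Each was tested with limma camera with the correlation between genes estimated, adjusted over the lists within a comparison. Counts of called members are given from the adjustment over all genes and from 1 over the list alone. Overlaps between treatments were set beside the product expected for independent lists and beside 50 simulations of unchanged groups that share 3 simulated controls. The simulated libraries used deviations from the group means, resampled over all 21 libraries. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 served for tables and figures.

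Named genes follow a rule written before the data were examined. It takes rpn-6.1 first, then the 6 largest rises and 6 largest falls of a comparison (gene symbol given, mean of at least 5 FPKM in a group, no overlap between the groups), then up to 4 called members of a described list in its commoner direction and 2 in the other, and 25 fixed genes. From these the text names mainly genes whose call held when each library was left out in turn, a restriction added after the data were seen. The result of 1 gene that the rule names is not reported here. Functions given with gene names are general knowledge and not measured here.

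The fit was tested on simulated data with 200 changed genes among 17492. Of genes changed 1.5-fold, 16% to 30% were recovered, of those changed 2-fold 40% to 56%, 4-fold 68% to 88% and 8-fold 86% to 98%, with 1 to 11 false calls per comparison. These rates belong to that number of changed genes and not to comparisons where more genes change. In these simulated data, where genes varied independently, camera gave an unadjusted p under 0.05 for 8 of 8 raised lists and 0 of 8 unchanged ones. Members of the real lists vary together, so this says nothing about the power of camera there. The alternatives were a pseudocount of 0.1, no filter, a filter at 5 FPKM, median-of-ratios scaling, quantile normalization, array weights, a fit of only the 2 groups, a replicate block, each library left out, camera with a preset correlation of 0.01, and fry. Added after the data were seen were leaving out the 3 libraries that stand apart, counts of the lists with 1 of these 3 left out, treating the zeros above as missing, and the families of genes in the closing part. No library was left out of the results reported.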

Results

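The series holds 21 RNA-seq libraries from C. elegans N2 adults on day 1 of adulthood, grown at 20 °C: 7 groups with 3 libraries each. The groups are untreated controls (replicates 4, 6 and 7), starvation for 15 h (1, 2 and 3), 200 µM fluphenazine (2, 4 and 9), 200 µM cantharidin (1, 3 and 9), rpn-6 RNAi from L3 (4, 5 and 6), bortezomib at 10 µM (7, 8 and 9) and bortezomib at 25 µM (3, 4 and 6). Drugs were given from L4 until the next day. The labels give the controls as not treated and name no vehicle group and no empty-vector RNAi group, so the comparisons do not separate a treatment from its vehicle or from RNAi feeding. Depth relative to control 4 ran from 0.943 to 1.499, a 1.59-fold range. The absolute depth was not given in the sources used here. Of 46254 gene IDs, 17492 reached 1 FPKM in at least 3 libraries and were tested, 16022 of them protein coding. All 21 libraries entered 1 limma fit. Fold changes are log2 values with their standard error (SE), p-values are adjusted over the 17492 genes, levels are mean FPKM with the SD, and n = 3 per group throughout. Where a group is near 0 FPKM the added constant of 1 sets the size of the fold change, which is then not the ratio of the printed means. The p-values measure spread between samples of a group, with 1 estimate per gene pooled over the 7 groups. A library that stands apart in 1 group can therefore also widen the SE in comparisons that do not hold it. Genes that vary in such a library can thus go uncalled elsewhere. Nothing in the labels says whether the 3 libraries of a group are separate cultures or technical repeats.

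Against control, the all-gene median moved up in every treatment: log2 0.38 in starvation, 0.34 in fluphenazine, 0.34 in cantharidin, 0.31 in rpn-6 RNAi, 0.16 in 10 µM and 0.40 in 25 µM bortezomib. The share of calls that were higher was 68% in starvation, 78.5% in fluphenazine, 84.3% in cantharidin, 76% in rpn-6 RNAi, 74.8% in 10 µM and 79.3% in 25 µM bortezomib. With median-of-ratios scaling the same shares were 49.5%, 45.3%, 49.3%, 51%, 38.4% and 52.7%, and with quantile normalization 42%, 37.8%, 38.3%, 46.1%, 41.6% and 40.9%. Which direction holds more genes therefore depends on the scaling, and the paragraphs on each treatment turn to genes and lists whose direction can be read against the all-gene shift. Counts of list members are to be read beside the share of all tested genes that was called. That share was 57.5% in starvation, 43.8% in fluphenazine, 37.9% in cantharidin, 36.7% in rpn-6 RNAi, 12.9% in 10 µM and 53.4% in 25 µM bortezomib.

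**Figure D1:**
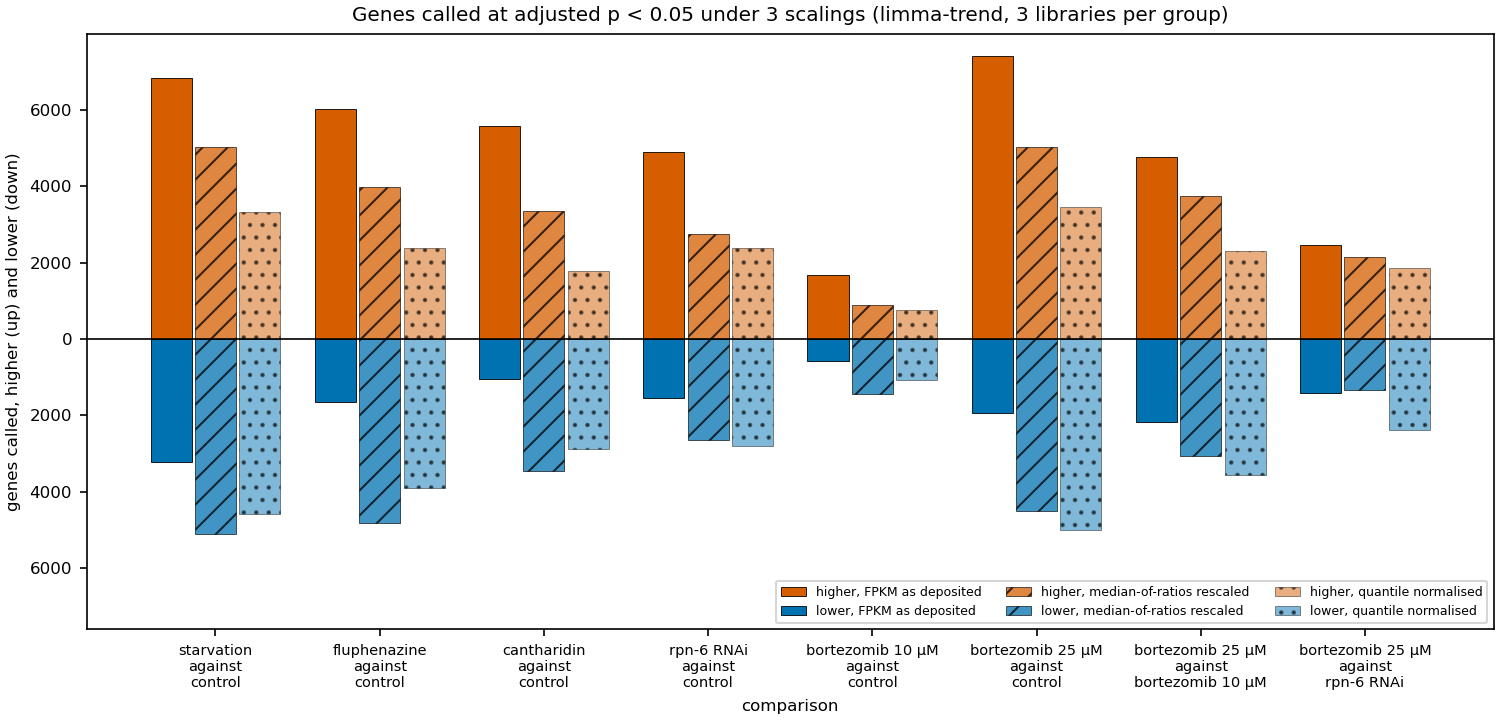
Number of genes called at adjusted p < 0.05 (y axis, higher upward and lower downward) for the 8 comparisons (x axis), with bars for the FPKM values as deposited, median-of-ratios scaling and quantile normalization. For starvation the 3 bars upward are 6843, 5013 and 3321 genes, and for 10 µM bortezomib 1681, 896 and 765.

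In all, 3 libraries stood apart from their groups. Control 7 had a mean correlation of 0.938 with the other controls and lay closest to a 10 µM bortezomib library (r = 0.951), while control 4 and 6 had r = 0.986 with each other. Fluphenazine 4 correlated at 0.891 with its own group and at 0.932 with the controls, and starvation 3 at 0.843 with its own group. The lists that set them apart differ; list levels are log2 values relative to the mean of the controls. Control 7 was at 1.24 in cuticle collagens (control 4 and 6 at -0.60 and -0.63) and 0.95 in sperm genes (-0.55 and -0.40). The collagen col-49, for one, stood at 6.38, 6.83 and 107.6 FPKM in control 4, 6 and 7. Fluphenazine 4 was at -0.36 in cuticle collagens (1.85 and 2.08 in fluphenazine 2 and 9) and 0.12 in oocyte genes (-1.43 and -2.05). Starvation 3 was at -9.06 in vitellogenins (-4.71 and -4.14 in starvation 1 and 2), at -3.85 in oocyte genes (-1.82 and -1.28) and at -1.80 in sperm genes (1.46 and 1.61). Control 7 also stood apart in proteasome subunits (-0.32 against 0.14 and 0.18), muscle genes (0.42 against -0.23 and -0.19), antimicrobial genes (0.32 against -0.16 and -0.16), ABC transporters (0.31 against -0.16 and -0.16) and PP1 and PP2A genes (-0.27 against 0.14 and 0.12), so counts of these lists against control depend in part on it, and are given without it in places. The level of proteasome subunits is a mean that includes pas-5, listed at 0 in 9 libraries. Whether such zeros make up part of the gaps in this list, here and in the treated groups, was not tested. In the plot of principal components, the first 3 hold 34%, 24% and 13.1% of the variance.

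**Figure D2:**
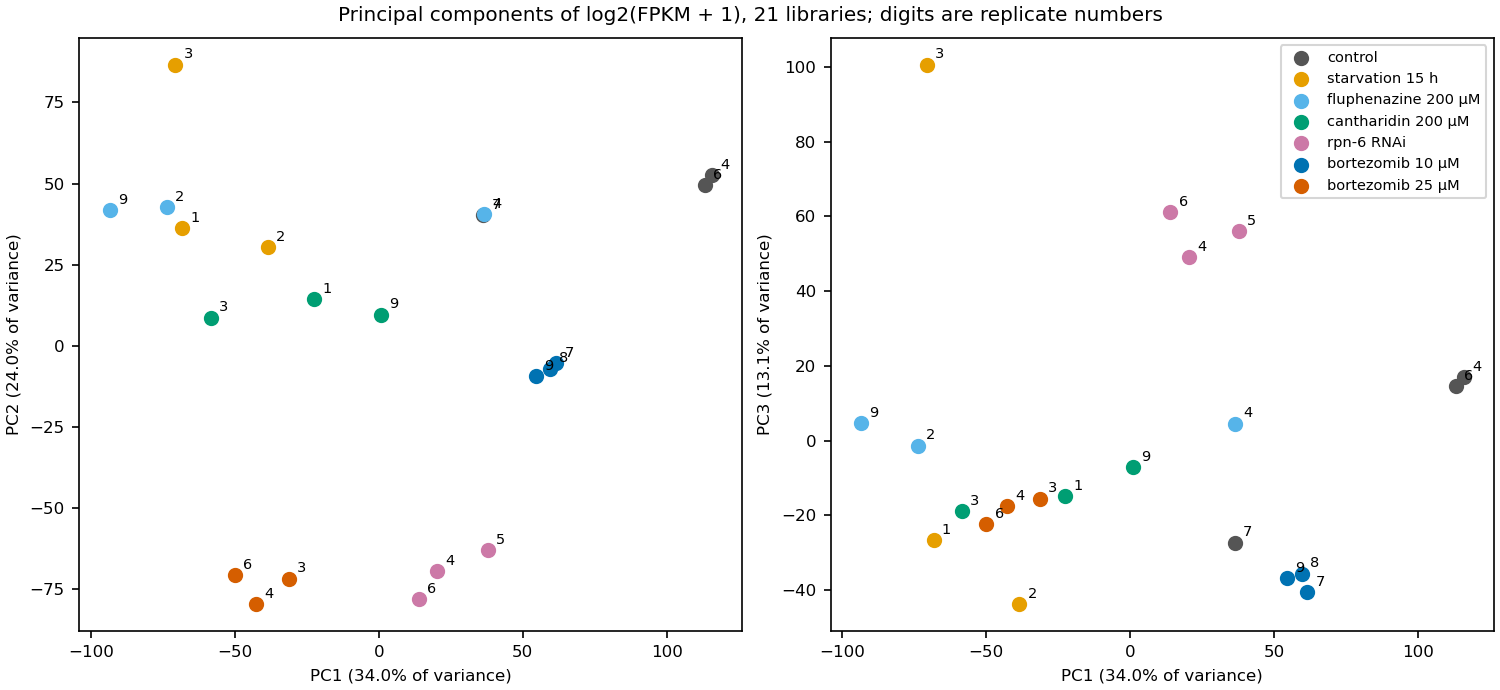
Principal components of log2(FPKM + 1) for the 21 libraries, 1 point per library with its replicate number; the x axis is component 1 (34% of variance) and the y axes are components 2 (24%) and 3 (13.1%). Control 4 and 6 lie at 115.8 and 113.2 on component 1, control 7 at 36.3, and starvation 3 at 100.6 on component 3.

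What does starvation for 15 h change in day 1 adults? Genes of fat breakdown were among the largest rises and yolk genes among the largest falls. lipl-3 (WBGene00020016), a lysosomal lipase, rose by 6.29 ± 0.16 (102.5 ± 11.8 against 0.321 ± 0.152 FPKM; adjusted p = 5.22e-13), and acs-2, which activates fatty acids for mitochondrial oxidation, rose by 5.76 ± 0.34 (545.2 ± 152 against 9.96 ± 6.57 FPKM). The flavin monooxygenase gene fmo-2 rose by 5.88 ± 0.51 (adjusted p = 1.88e-07). On the lower side the yolk protein gene vit-3 (WBGene00006927) changed by -8.24 ± 0.70 (adjusted p = 1.75e-07; 2.94 ± 2.57 against 982.5 ± 152 FPKM), vit-4 by -7.62 ± 0.81 and vit-1 by -7.37 ± 0.64. In all, 10066 genes were called (6843 higher and 3223 lower; 5013 and 5107 with median-of-ratios scaling, 3321 and 4581 with quantile normalization), and 5172 of them changed at least 2-fold. The all-gene median was 0.38, so a gene at that value kept pace with the rest.

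Among 84 fasting and fat metabolism genes, 36 higher and 23 lower were called (37 and 24 adjusted over the list alone). icl-1, the glyoxylate cycle enzyme that turns fat into sugar, rose by 3.53 ± 0.20 (adjusted p = 2.63e-09), and the palmitoyl-CoA desaturase gene fat-5 rose by 3.91 ± 0.40 (adjusted p = 1.10e-06). By contrast the stearoyl-CoA desaturase gene fat-7 fell (-4.83 ± 0.34, adjusted p = 2.09e-08), as did the acyl-CoA dehydrogenase gene acdh-2 (0.142 ± 0.071 against 72.3 ± 5.04 FPKM, adjusted p = 4.51e-09). The list median was 0.44, yet camera pointed down (adjusted p = 0.947 with an estimated correlation), so median and test differ in sign. Of 78 autophagy and lysosome genes, 28 higher and 21 lower were called (28 and 21 adjusted over the list alone). sqst-1, the receptor that carries ubiquitinated cargo to autophagosomes, rose by 2.30 ± 0.17 (adjusted p = 2.78e-08), and the cathepsin B genes cpr-4 and cpr-9 moved apart at 2.28 ± 0.29 and -2.09 ± 0.13. daf-16, the FOXO factor of insulin signalling, rose by 1.05 ± 0.08 (adjusted p = 6.16e-08), and the metallothionein gene mtl-1 by 4.58 ± 0.48 (adjusted p = 1.61e-06). tts-1, a long noncoding RNA, rose by 5.37 ± 0.19 to 2357 FPKM.

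Of 38 oocyte and eggshell genes, 36 fell and 0 rose (list median -2.35, -2.73 relative to all genes; 0 and 36 adjusted over the list alone; adjusted p = 0.57 with an estimated correlation). Examples are the germ granule gene meg-1 (-3.84 ± 0.82), oma-2, needed for oocyte maturation (-3.37 ± 0.65), and the yolk receptor gene rme-2 (-2.99 ± 0.67, adjusted p = 0.00158; not called in a fit of the 2 groups alone). Libraries stand apart here: starvation 3 was at a list level of -3.85 against -1.82 and -1.28, and control 7 at -0.53 against 0.27 and 0.27. Among 38 germline genes the calls were 6 higher and 17 lower (median -0.19), but 9 higher and 9 lower without starvation 3 (median -0.02); the replication licensing gene mcm-7 fell (-1.59 ± 0.37, adjusted p = 0.00237) and the synapsis gene syp-1 rose (1.03 ± 0.13). Early embryo genes gave 1 higher and 5 lower of 14, with tbx-9, a T-box factor, at -3.10 ± 0.62, and control 7 (-0.84) was close to the starved libraries (-0.92, -0.91 and -0.96); the calls were 1 higher and 12 lower without control 7 and 1 higher and 3 lower without starvation 3. Of 6 vitellogenins, 5 fell, and 6 did so adjusted over the list alone (adjusted p = 0.57 with an estimated correlation), with starvation 3 at -9.06 against -4.71 and -4.14.

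Of 34 proteasome subunits, 30 were lower and 1 higher (median -0.58, -0.96 relative to all genes; the same counts adjusted over the list alone; adjusted p = 0.57 with an estimated correlation): the core subunit pas-2 changed by -1.04 ± 0.12 (adjusted p = 5.79e-06; 178.5 ± 12 against 370.8 ± 46.1 FPKM) and the ATPase subunit rpt-4 by -0.79 ± 0.12. Control 7 (-0.32) lay nearer to the starved libraries (-0.48, -0.42 and -0.49) than the other controls did; without it the calls were 1 higher and 30 lower (median -0.67). In the ubiquitin system (43 genes, 11 higher and 17 lower) the conjugating enzyme gene ubc-8 rose by 2.57 ± 0.13 (adjusted p = 8.06e-10) and the SUMO conjugating enzyme gene ubc-9 fell (-1.06 ± 0.20). Cytosolic heat shock genes gave 2 higher and 17 lower of 31, with the constitutive HSP70 gene hsp-1 at -0.63 ± 0.11 (adjusted p = 2.71e-04). hsp-60, the mitochondrial chaperonin, fell (-1.91 ± 0.14, adjusted p = 2.68e-08; 99.5 ± 21.8 against 369.8 ± 36.9 FPKM), and 7 of 11 mitochondrial stress genes fell while 3 rose. Of 20 ER stress genes 16 were not called (adjusted p = 0.879 with an estimated correlation); 2 higher and 2 lower were called with all libraries and 1 higher and 8 lower without starvation 3, so the count rests on that library. The secreted neurotrophic factor gene manf-1 fell (-0.79 ± 0.10).

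Of 55 neuropeptides and neuronal genes, 50 rose and 1 fell (median 1.55, 1.17 relative to all genes; adjusted p = 0.57 with an estimated correlation), among them the FMRFamide-like genes flp-27 (2.42 ± 0.18), flp-3 (2.37 ± 0.15) and flp-12 (2.29 ± 0.19). Of 148 cuticle collagens 78 higher and 15 lower were called (median 1.93; adjusted p = 0.947 with an estimated correlation), a list in which control 7 stands apart; the calls were 44 higher and 7 lower without starvation 3 and 90 higher and 8 lower without control 7. col-65 rose by 4.54 ± 1.01 (adjusted p = 0.00155) and col-101 fell (-3.95 ± 0.71). Drug metabolism genes moved both ways. Calls were 33 higher and 13 lower of 66 cytochrome P450 genes, with cyp-37B1 at 4.63 ± 0.22 and cyp-35C1 at -3.19 ± 0.38, and 19 higher and 18 lower of 64 UDP-glucuronosyltransferases, with ugt-18 at 3.68 ± 0.30 and ugt-22 at -3.43 ± 0.18. Among 92 antimicrobial genes (33 higher and 14 lower), the saposin-like genes spp-6 and spp-23 stood at 3.46 ± 0.35 and -5.15 ± 0.26. The share higher in this list is no larger than the 6843 of 17492 over all genes. Ribosomal protein genes (79) gave 31 higher and 2 lower calls with a median of 0.21, which turned to -0.17 with median-of-ratios scaling and 0.11 with quantile normalization; without starvation 3 the calls were 10 higher and 1 lower, and without control 7 50 higher and 2 lower. With 1 library left out the number of called genes ran from 7518 without control 4 to 11020 without control 7.

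What does fluphenazine, a phenothiazine antipsychotic, change at 200 µM? Cytochrome P450 genes made up 5 of the 6 largest rises. cyp-35B3 (WBGene00019470) rose by 9.54 ± 0.14 (913.9 ± 149 against 0.216 ± 0.0581 FPKM; adjusted p = 2.69e-17), cyp-35B2 by 9.54 ± 0.11, cyp-33C6 by 7.11 ± 0.16, cyp-35B1 by 7.09 ± 0.28 and cyp-35A1 by 6.53 ± 0.27. pgp-13 (WBGene00004007), a P-glycoprotein drug exporter, rose by 6.13 ± 0.19 (154.5 ± 50.2 against 1.14 ± 0.156 FPKM; adjusted p = 1.91e-12). Yolk and fat genes changed as well: vit-3 by -6.33 ± 0.70 (adjusted p = 3.82e-06), vit-4 by -5.82 ± 0.81, the acyl-CoA dehydrogenase gene acdh-2 by -5.43 ± 0.36 and the desaturase gene fat-7 by -4.55 ± 0.34 (adjusted p = 5.23e-08). The counts were 7658 called genes, 6015 higher and 1643 lower, against 3989 and 4814 with median-of-ratios scaling and 2369 and 3902 with quantile normalization. At least 2-fold changes numbered 3892, and the all-gene median was 0.34.

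Across 66 cytochrome P450 genes, 36 rose, 6 fell and 24 were not called (38 and 6 adjusted over the list alone; 43 higher and 10 lower without fluphenazine 4); the median was 0.81, 0.47 relative to all genes, with adjusted p = 0.528 with an estimated correlation. cyp-35D1 and cyp-25A1 went the other way at -2.33 ± 0.36 (not called in a fit of the 2 groups alone) and -1.79 ± 0.31. In the conjugation step, 23 of 64 UDP-glucuronosyltransferases rose and 12 fell (ugt-36 3.98 ± 0.21, ugt-43 3.06 ± 0.27, ugt-22 -1.96 ± 0.18), a list whose median of 0.34 became 0.01 with median-of-ratios scaling and -0.29 with quantile normalization; without fluphenazine 4 the calls were 30 higher and 7 lower (median 0.50). Of 29 ABC transporters 9 higher and 2 lower were called, with pgp-14 at 2.96 ± 0.32 and the multidrug resistance gene mrp-2 at 1.74 ± 0.20. Their median was 0.27 and -0.11 with median-of-ratios scaling and -0.34 with quantile normalization. Without fluphenazine 4 it was 0.54, with 14 higher and 3 lower, and without control 7 0.62. Glutathione S-transferases gave 15 higher and 15 lower of 50: gsto-2, an omega-class enzyme, rose by 1.83 ± 0.24 (adjusted p = 1.80e-05), while gst-10 fell (-3.06 ± 0.23) and gst-4, a reporter of SKN-1 activity, fell (-1.29 ± 0.16, adjusted p = 1.11e-05). mtl-1, a metallothionein, rose by 5.60 ± 0.48 (91.5 ± 45 against 0.971 ± 1.12 FPKM), and cdr-1, a cadmium-responsive gene, by 1.91 ± 0.26; 7 higher and 2 lower of 14 metallothionein and osmotic stress genes were called (adjusted p = 0.648 with an estimated correlation), with a median of 0.38 that was 0.90 without fluphenazine 4.

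Of 92 antimicrobial genes 43 higher and 11 lower were called (46 and 11 adjusted over the list alone; median 1.17; adjusted p = 0.648 with an estimated correlation). The fungus-induced peptide gene fipr-26 rose by 6.15 ± 0.71 (adjusted p = 5.65e-06) and the caenacin gene cnc-11 by 5.69 ± 0.53, while the saposin-like genes spp-17 and spp-23 fell (-4.54 ± 0.43 and -4.34 ± 0.26). C-type lectins gave 80 higher and 10 lower of 158 (82 and 12 adjusted over the list alone; adjusted p = 0.701 with an estimated correlation), among them clec-17 at 3.80 ± 0.45 and clec-190 at -3.94 ± 0.44. tir-1, the adaptor upstream of the p38 immune pathway, rose by 1.69 ± 0.20 (adjusted p = 8.22e-06). In both lists fluphenazine 4 stands apart, at 0.51 against 1.36 and 1.29 in antimicrobial genes and 0.32 against 1.00 and 0.96 in lectins. Without it the calls were 55 higher and 11 lower (median 1.34) and 92 higher and 15 lower (0.94).

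acs-2 rose by 4.81 ± 0.34 (283.8 ± 78.2 against 9.96 ± 6.57 FPKM), the glyoxylate cycle gene icl-1 by 2.53 ± 0.20, lipl-3 by 3.14 ± 0.16 and sqst-1 by 2.50 ± 0.17 (adjusted p = 1.67e-08); 29 higher and 17 lower of 84 fasting and fat metabolism genes were called, with a median of 0.30 that became -0.12 with median-of-ratios scaling and 0.01 with quantile normalization. Of 78 autophagy and lysosome genes 30 higher and 13 lower were called. The median was 0.10 and turned to -0.30 with median-of-ratios scaling and 0.01 with quantile normalization. Neuropeptides and neuronal genes gave 50 higher and 0 lower of 55 (52 and 0 adjusted over the list alone; adjusted p = 0.528 with an estimated correlation), such as flp-8 at 2.48 ± 0.19 and flp-18 at 2.16 ± 0.17. On the lower side, 29 of 34 proteasome subunits fell and 0 rose (1 and 32 adjusted over the list alone, median -0.45; adjusted p = 0.52 with an estimated correlation), for example pas-2 at -0.75 ± 0.12 (adjusted p = 2.05e-04). Fluphenazine 4 (-0.11) lay apart from fluphenazine 2 and 9 (-0.47 and -0.53); the median was -0.63 without it and -0.57 without control 7. The mitochondrial chaperonin gene hsp-60 fell (-1.42 ± 0.14, adjusted p = 8.44e-07), and 7 of 26 muscle genes fell against 3 higher, with the troponin T gene tnt-2 at -1.17 ± 0.14. The muscle counts rest on single libraries: they were 6 higher and 6 lower without control 7 and 6 higher and 6 lower without fluphenazine 4.

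The number of oocyte genes called depends on single libraries. It was 0 higher and 3 lower of 38 with all libraries, 0 higher and 33 lower without fluphenazine 4 (median -1.76) and 0 higher and 15 lower without control 7. With all libraries 0 were called adjusted over the list alone, although the list median was -1.12 (fluphenazine 4 at a list level of 0.12 against -1.43 and -2.05). The count of called genes was 4560 without fluphenazine 9, 4873 without fluphenazine 2 and 11010 without fluphenazine 4, the library that stood nearer the controls.

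What does cantharidin, an inhibitor of the PP1 and PP2A phosphatases, change at 200 µM? Antimicrobial peptide genes were among the largest rises. cnc-11 (WBGene00044900) rose by 6.64 ± 0.53 (99 ± 5.93 against 0 ± 0 FPKM; adjusted p = 1.55e-07; 9.95 with a pseudocount of 0.1, so the size is set by that constant), the neuropeptide-like gene nlp-34 by 6.05 ± 0.47, cnc-4 by 5.96 ± 0.37 and cnc-6 by 5.35 ± 0.19 (adjusted p = 6.98e-11). Members of the pud family were among the largest falls: pud-3 (WBGene00017501) changed by -8.18 ± 0.68 (0.512 ± 0.12 against 471.1 ± 212 FPKM; adjusted p = 2.18e-07), pud-4 by -7.18 ± 0.55 and pud-1.1 by -6.67 ± 0.64. pud-2.2 has 2 near-identical copies, WBGene00017500 and WBGene00017490, whose values of -7.21 ± 0.62 and -7.20 ± 0.62 are uncertain as to which copy changed. In total 6628 genes were called, 5586 higher and 1042 lower (3355 and 3455 with median-of-ratios scaling, 1790 and 2888 with quantile normalization), 3399 of them at least 2-fold. The all-gene median was 0.34.

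Of 92 antimicrobial genes 47 higher and 9 lower were called (50 and 9 adjusted over the list alone), with a median of 1.25, 0.91 relative to all genes, and adjusted p = 0.626 with an estimated correlation. fipr-26 rose by 5.46 ± 0.71, and the saposin-like genes spp-4 and spp-17 fell (-3.25 ± 0.26 and -2.92 ± 0.43). tir-1, the adaptor upstream of p38 signalling, rose by 2.26 ± 0.20 (adjusted p = 4.02e-07). Of 158 C-type lectins 72 rose, for instance clec-67 (4.62 ± 0.54), and 12 fell. Intracellular pathogen response genes, a set induced by microsporidia and by proteasome block, gave 23 higher and 0 lower of 40 (25 and 0 adjusted over the list alone; adjusted p = 0.545 with an estimated correlation), with pals-6 at 3.35 ± 0.46, pals-31 at 3.14 ± 0.20 and the ubiquitin ligase cullin gene cul-6 at 2.20 ± 0.20 (adjusted p = 5.15e-07).

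Among energy genes, 39 of 50 respiratory chain genes fell and none rose (0 and 42 adjusted over the list alone; median -0.39, -0.73 relative to all genes). This was 1 of the 4 list calls of the series (adjusted p = 0.0472 with an estimated correlation), and it held in 6 of 15 other settings. It was lost without control 7 (0.196), without cantharidin 3 (0.058) and without cantharidin 9 (0.0969), with median-of-ratios scaling (0.412), quantile normalization (0.538) and the filter at 5 FPKM (0.0696), and in a fit of the 2 groups alone (0.211). The complex III gene ucr-2.2 fell (-0.73 ± 0.17, adjusted p = 0.00374), and so did the cytochrome c oxidase genes cox-6C (-0.67 ± 0.09) and cox-17 (-0.63 ± 0.09) and the complex I gene gas-1 (-0.60 ± 0.13). hsp-60 fell (-1.04 ± 0.14, adjusted p = 2.20e-05), whereas atfs-1, the factor that drives the mitochondrial stress response, rose by 0.69 ± 0.11 (0.27 and not called with median-of-ratios scaling). The mitochondrial stress list gave 2 higher and 5 lower of 11. Fat genes divided into 21 higher and 19 lower of 84, with the enoyl-CoA hydratase gene ech-9 at 4.79 ± 0.26 and acs-2 at 3.85 ± 0.34 against fat-7 at -5.22 ± 0.34 and acdh-2 at -5.08 ± 0.36 (adjusted p = 4.46e-08). Of 6 vitellogenins 4 fell, among them vit-3 (-6.74 ± 0.70, adjusted p = 2.02e-06) and vit-4 (-6.23 ± 0.81).

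Of the phosphatase genes that the drug targets, 1 of 17 PP1 and PP2A genes rose and none fell (0 and 0 adjusted over the list alone), with a median of -0.10. In protein quality control, 29 of 34 proteasome subunits fell and 0 rose (1 and 32 adjusted over the list alone; median -0.40; adjusted p = 0.29 with an estimated correlation), such as pas-2 at -0.58 ± 0.12. Without control 7 the calls were 1 higher and 31 lower (median -0.51). Of 20 ER stress genes 7 rose and 0 fell; the unfolded protein response factor gene xbp-1 rose by 1.01 ± 0.12 (adjusted p = 9.97e-06). The list median of 0.36 became -0.06 with median-of-ratios scaling and 0.37 with quantile normalization. sqst-1 rose by 3.02 ± 0.17 (174.7 ± 21.9 against 20.9 ± 5.05 FPKM) and the cathepsin B gene cpr-3 by 3.79 ± 0.27, in a list of 78 autophagy and lysosome genes with 20 higher and 10 lower. ugt-18 rose by 5.01 ± 0.30 and the half-transporter gene haf-7 by 2.59 ± 0.21; ABC transporters gave 14 higher and 1 lower of 29 (adjusted p = 0.644 with an estimated correlation). The 2 copies of numr-1, a metal-responsive gene, rose by 3.76 ± 0.32 (WBGene00017270) and 2.93 ± 0.32 (WBGene00017267), and their separation is uncertain. Neuronal genes gave 48 higher and 0 lower of 55, with flp-13 at 1.51 ± 0.22. Sperm genes gave 18 higher and 0 lower of 87, a smaller share higher than the 5586 of 17492 over all genes. Adjusted over the list alone the calls were 0 and 0. Control 7 (0.95) lay near the cantharidin libraries, and 28 were higher without it. The number of called genes was 4319 without cantharidin 3 and 7739 without control 7.

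What does rpn-6 RNAi from L3 change? The target transcript comes first: rpn-6.1 (WBGene00004462), the 19S subunit gene also called rpn-6, read 114.8, 121.7 and 127.1 FPKM in the 3 RNAi libraries against 167.9, 168.2 and 130.2 in the controls, a log2 difference of -0.35 ± 0.14 (adjusted p = 0.0553) that was not called. Its level was no lower than in starved worms (112.1, 122.1 and 121.2 FPKM). In starvation, however, 30 of 34 proteasome subunits were lower, whereas under RNAi 28 were higher and 0 lower with the FPKM as deposited. The result for rpn-6.1 depends on 1 library and on the scaling: it was called without control 7 (-0.47, adjusted p = 0.015), with median-of-ratios scaling (-0.72, adjusted p = 0.00407) and with quantile normalization (-0.43, adjusted p = 0.024). Other genes changed strongly. eol-1 (WBGene00045401), a decapping exoribonuclease homolog of the intracellular pathogen response, rose by 7.94 ± 0.22 (358.6 ± 33.4 against 0.467 ± 0.211 FPKM; adjusted p = 7.06e-14), ddn-1 by 7.59 ± 0.24, pals-39 by 7.54 ± 0.56 and pals-10 by 7.47 ± 0.20. acdh-1 (WBGene00016943), a short-chain acyl-CoA dehydrogenase, changed by -8.51 ± 0.91 (1.76 ± 1.2 against 949 ± 76.7 FPKM; adjusted p = 1.13e-06). The counts were 6425 called, 4884 higher and 1541 lower (2752 and 2647 with median-of-ratios scaling, 2391 and 2799 with quantile normalization), 2997 of them at least 2-fold, with an all-gene median of 0.31.

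In the intracellular pathogen response, 35 of 40 members rose and none fell (38 and 0 adjusted over the list alone), with a median of 4.78, 4.47 relative to all genes. Camera called it (adjusted p = 0.0268 with an estimated correlation; 0.0653 without control 7 and 0.17 in a fit of the 2 groups alone, 0.00921 and 0.00219 with the other scalings). pals-14 rose by 7.18 ± 0.37 and pals-3 by 7.06 ± 0.20 (adjusted p = 8.18e-14), and the cullin gene cul-6, part of the same response, by 3.13 ± 0.20 (27.9 ± 4.86 against 2.3 ± 0.598 FPKM).

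Small heat shock genes rose too, by less than eol-1 and pals-10. hsp-16.41 rose by 6.81 ± 0.31 (adjusted p = 3.75e-11), hsp-16.2 by 6.45 ± 0.25 (380.2 ± 18.6 against 3.38 ± 0.396 FPKM) and hsp-70, the inducible HSP70, by 5.30 ± 0.35 (adjusted p = 3.21e-09). Of 31 cytosolic heat shock genes 21 rose and 0 fell (22 and 1 adjusted over the list alone; median 0.51; adjusted p = 0.113 with an estimated correlation). hsp-16.1 has 2 near-identical copies, and the value of 5.32 ± 0.22 at WBGene00002015 is uncertain as to copy. Of 34 proteasome subunits 28 rose and 0 fell (28 and 1 adjusted over the list alone), with rpt-6 at 0.73 ± 0.07 (adjusted p = 6.61e-07), rpn-10 at 0.65 ± 0.09 and rpn-11 at 0.62 ± 0.13. That rise depends on the scaling: the median of 0.43 is 0.50 with quantile normalization, but 0.12 relative to all genes and 0.05 with median-of-ratios scaling, where 1 subunit was higher and 1, rpn-6.1, lower (adjusted p = 0.703 with an estimated correlation). Control 7 (-0.32) lay below control 4 and 6 (0.14 and 0.18), which were near the RNAi libraries (0.27, 0.24 and 0.21); without it the calls were 17 higher and 2 lower (median 0.35). With median-of-ratios scaling rpn-10 (0.27), rpn-11 (0.25), skn-1 (0.36) and ubq-1 (0.39) were not called. skn-1, the gene of a factor that drives subunit genes, rose by 0.73 ± 0.10 (adjusted p = 2.76e-05), the protease gene ddi-1, which activates that factor, by 1.06 ± 0.17, and ubq-1 by 0.77 ± 0.13. In the ubiquitin system 21 higher and 2 lower of 43 were called, and the median of 0.36 became -0.01 with median-of-ratios scaling and 0.14 with quantile normalization.

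Of 50 glutathione S-transferases 25 rose and 7 fell (26 and 8 adjusted over the list alone; adjusted p = 0.4 with an estimated correlation): gst-24 by 5.74 ± 0.26, gst-30 by 4.45 ± 0.37 and the SKN-1 reporter gst-4 by 2.32 ± 0.16 (338.7 ± 2.23 against 67 ± 2.11 FPKM; adjusted p = 5.66e-09). Of 66 cytochrome P450 genes 10 higher and 17 lower were called, with cyp-35A2 at -4.49 ± 0.44 (adjusted p = 4.01e-07), and of 64 UDP-glucuronosyltransferases 15 higher and 22 lower, with ugt-53 at -3.41 ± 0.17. The P-glycoprotein gene pgp-8 rose by 5.07 ± 0.17 and the cadmium-responsive gene cdr-4 by 4.30 ± 0.16. numr-1 rose by 7.24 ± 0.32 at WBGene00017270 and 6.47 ± 0.32 at WBGene00017267, uncertain as to copy.

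Fasting and fat metabolism genes were called as a list (adjusted p = 0.0268 with an estimated correlation; 0.0653 without control 7, 0.159 with quantile normalization and 0.0619 in a fit of the 2 groups alone), with 15 higher and 35 lower of 84, 15 and 36 adjusted over the list alone, and a median of -0.13. acdh-2 (-4.55 ± 0.36) and the elongase gene elo-6 (-3.38 ± 0.22) fell, and acs-2 rose (3.89 ± 0.34). Respiratory chain genes, the remaining list call, gave 0 higher and 37 lower of 50 (0 and 38 adjusted over the list alone; median -0.37; adjusted p = 0.0429 with an estimated correlation), lost without control 7 (0.0684), without control 6 (0.0517) and without rpn-6 RNAi 5 (0.0507). It was also lost with median-of-ratios scaling (0.273), quantile normalization (0.385) and the filter at 5 FPKM (0.056), and in a fit of the 2 groups alone (0.228). ucr-2.2 fell (-1.24 ± 0.17), as did gas-1 (-0.97 ± 0.13). The folate transporter gene folt-2 fell (-5.08 ± 0.39, adjusted p = 2.30e-08), and the aspartyl protease gene asp-13 at -5.45 ± 0.56 leads a lysosome list with 26 higher and 34 lower of 78. Of 79 ribosomal protein genes 71 fell, such as rps-23 (-0.44 ± 0.08), and 1 rose. The median of -0.34 became -0.72 with median-of-ratios scaling and 0.02 with quantile normalization, where rps-23 (-0.04) was not called; 47 fell without control 7. The neuropeptide gene flp-34 rose by 4.64 ± 0.29 (adjusted p = 2.20e-09) among 39 higher of 55 neuronal genes. Leaving out 1 library gave between 5216 and 6073 called genes.

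What does bortezomib, an inhibitor of the 20S proteasome, change at 10 µM? Small heat shock genes rose most: hsp-16.41 (WBGene00002018) by 5.70 ± 0.31 (219.1 ± 16.1 against 3.26 ± 0.76 FPKM; adjusted p = 6.22e-09), hsp-16.2 by 5.65 ± 0.25 and the inducible HSP70 gene hsp-70 by 3.76 ± 0.35 (adjusted p = 2.46e-06). The near-identical copies of hsp-16.1 (WBGene00002015 at 4.74 ± 0.22, WBGene00002017 at 4.51 ± 0.21) and hsp-16.48 (WBGene00002020 at 4.44 ± 0.24, WBGene00002019 at 4.43 ± 0.24) rose too, uncertain as to copy. The pud genes fell again, with pud-3 at -8.31 ± 0.68 (0.38 ± 0.145 against 471.1 ± 212 FPKM), pud-4 at -7.09 ± 0.55, pud-1.1 at -6.82 ± 0.64 and pud-1.2 at -6.70 ± 0.62 (adjusted p = 2.76e-06). The response was the smallest of the 6: 2248 genes called, 1681 higher and 567 lower (896 and 1437 with median-of-ratios scaling, 765 and 1076 with quantile normalization), 943 at least 2-fold, and an all-gene median of 0.16.

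Of 34 proteasome subunits, 27 rose and 0 fell (32 and 0 adjusted over the list alone; median 0.51, 0.35 relative to all genes; adjusted p = 0.417 with an estimated correlation): rpt-6 by 0.73 ± 0.07 (307.2 ± 9.88 against 185 ± 12 FPKM; adjusted p = 6.35e-06), rpn-8 by 0.67 ± 0.10, rpn-10 by 0.60 ± 0.09 and the core subunit pas-1 by 0.58 ± 0.11. With quantile normalization the median was 0.51, and with median-of-ratios scaling it was 0.23 and 1 subunit stayed called. Without control 7 the calls were 18 higher and 0 lower (median 0.42). skn-1 rose by 0.52 ± 0.10 and its activating protease gene ddi-1 by 0.70 ± 0.17 (adjusted p = 0.0136), and neither was called with median-of-ratios scaling (0.25 and 0.43). In the ubiquitin system 10 higher and 1 lower of 43 were called and 21 and 2 adjusted over the list alone; without control 7 they were 6 higher and 1 lower, and the median of 0.32 became 0.17. Cytosolic heat shock genes gave 14 higher and 0 lower of 31 (adjusted p = 0.0552 with an estimated correlation).

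Of 40 intracellular pathogen response genes 30 rose and 0 fell (34 and 0 adjusted over the list alone), with a median of 1.38; the adjusted p = 0.0552 with an estimated correlation was above the threshold and became 0.0478 without bortezomib 10 µM replicate 8 and 0.106 without control 7. Camera also called this list with no filter, with median-of-ratios scaling and with quantile normalization. It did not with the filter at 5 FPKM, with array weights or in a fit of the 2 groups alone. pals-14 rose by 3.81 ± 0.37 (adjusted p = 4.27e-06), pals-6 by 3.80 ± 0.46 and pals-5 by 2.79 ± 0.16. Of 50 respiratory chain genes 28 fell and 0 rose, at the same adjusted p of 0.0552 and the same 2 values without those libraries; 15 fell without control 7. Next, 16 of 50 glutathione S-transferases rose (gst-30 3.40 ± 0.37, gst-25 3.15 ± 0.22, gst-4 1.60 ± 0.16) and 5 fell (gst-42 -1.50 ± 0.21), with a median of 0.22 that became -0.02 with median-of-ratios scaling and -0.10 with quantile normalization. Cytochrome P450 genes gave 3 higher and 13 lower of 66, led by cyp-35A3 (-2.47 ± 0.36). cdr-4, the cadmium-responsive gene, rose by 2.76 ± 0.16 and acs-2 by 3.11 ± 0.34 (adjusted p = 1.39e-05), while the immune genes irg-4 (-4.24 ± 0.53) and spp-4 (-2.77 ± 0.26) fell.

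Of 148 cuticle collagens 1 fell, of 55 neuronal genes 4 rose (0 and 0 adjusted over the list alone), and 6 of 26 muscle genes fell. The muscle calls rest on control 7 (0.42 against -0.23 and -0.19 in control 4 and 6 and -0.28, -0.29 and -0.28 with the drug): without it 0 fell, and the median of -0.38 became -0.18. Ribosomal protein genes gave 0 higher and 63 lower of 79, rpl-25.2 among them (-0.45 ± 0.09), with a median of -0.30 that became -0.58 with median-of-ratios scaling and 0.02 with quantile normalization, where rpl-25.2 (-0.13) was not called; 14 fell without control 7. The count of called genes is sensitive to single libraries: 1494 without control 4, 1124, 1388 and 1162 without bortezomib 10 µM replicates 7, 8 and 9, and 2514 without control 7.

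What does bortezomib change at 25 µM? Among the largest rises were eol-1 by 7.44 ± 0.22 (252.2 ± 20.9 against 0.467 ± 0.211 FPKM; adjusted p = 3.23e-13), lys-3 (WBGene00003092), a lysozyme gene, by 7.30 ± 0.24 (229.8 ± 10.7 against 0.481 ± 0.271 FPKM; adjusted p = 9.51e-13) and the F-box gene fbxa-75 by 6.77 ± 0.16. The largest falls were pud-3 at -7.02 ± 0.68, vit-3 at -6.93 ± 0.70 (8.58 ± 7.29 against 982.5 ± 152 FPKM), vit-4 at -6.79 ± 0.81 and the folate transporter gene folt-2 at -6.70 ± 0.39 (adjusted p = 1.02e-09). Both copies of clec-209 (WBGene00018910 and WBGene00021224) read -6.41 ± 0.28, uncertain as to copy. The fit called 9333 genes, 7397 higher and 1936 lower (5016 and 4510 with median-of-ratios scaling, 3453 and 4998 with quantile normalization), 5184 at least 2-fold, with an all-gene median of 0.40.

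Of 40 intracellular pathogen response genes 39 rose and 0 fell (40 and 0 adjusted over the list alone), at a median of 3.71 and 3.31 relative to all genes (adjusted p = 0.0795 with an estimated correlation). Camera called this list with no filter and with quantile normalization, but not with median-of-ratios scaling. pals-39 rose by 6.90 ± 0.56, pals-3 by 6.50 ± 0.20 (adjusted p = 3.64e-13) and cul-6 by 2.48 ± 0.20. Antimicrobial genes gave 47 higher and 19 lower of 92 (49 and 21 adjusted over the list alone); the saposin-like gene spp-20 rose by 6.09 ± 0.26 and the invertebrate lysozyme gene ilys-5 fell (-6.36 ± 0.46, adjusted p = 1.21e-08). This list had a median of 0.95 and a mean of 0.80, but camera ranked it below other genes (adjusted p = 0.916 with an estimated correlation). C-type lectins split into 51 higher and 40 lower of 158, with a median of 0.05 and a mean of -0.02.

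rpn-6.1 read 218.2, 221.5 and 210.1 FPKM and rose by 0.49 ± 0.14 (adjusted p = 0.0066); 21 of 34 proteasome subunits rose and 0 fell (23 and 0 adjusted over the list alone), for example rpt-6 at 0.77 ± 0.07 (316.8 ± 19.7 against 185 ± 12 FPKM), rpn-10 at 0.65 ± 0.09 and rpn-8 at 0.64 ± 0.10. Their median of 0.34 is -0.06 relative to all genes and -0.11 with median-of-ratios scaling, but 0.32 with quantile normalization (adjusted p = 0.726 with an estimated correlation). Control 4 and 6 (0.14 and 0.18) were near the bortezomib libraries (0.14, 0.38 and 0.29) and control 7 (-0.32) was not; without control 7 the calls were 14 higher and 0 lower (median 0.25). With median-of-ratios scaling rpn-6.1 (0.03), rpn-8 (0.19) and rpn-10 (0.20) were not called. Heat shock genes gave 13 higher and 6 lower of 31, with a median of 0.16 that became -0.25 with median-of-ratios scaling and 0.12 with quantile normalization: hsp-16.41 rose by 5.34 ± 0.31 (adjusted p = 1.00e-09), hsp-16.2 by 5.14 ± 0.25 and hsp-70 by 2.97 ± 0.35, while the chaperonin gene cct-1 fell (-0.35 ± 0.09). hsp-60 fell (-1.93 ± 0.14, adjusted p = 1.04e-08) and 6 of 11 mitochondrial stress genes fell against 2 higher. Of 50 glutathione S-transferases 28 higher and 9 lower were called, gst-25 at 4.19 ± 0.22, gst-30 at 3.90 ± 0.37, gst-4 at 1.49 ± 0.16 and gst-26 at -2.84 ± 0.21, with a median of 0.73 that became 0.35 with median-of-ratios scaling and -0.20 with quantile normalization.

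Of 50 respiratory chain genes 43 fell and 0 rose (0 and 44 adjusted over the list alone; median -0.54; adjusted p = 0.0578 with an estimated correlation), with ucr-2.2 at -1.44 ± 0.17, gas-1 at -1.28 ± 0.13 and the ATP synthase gene atp-2 at -1.01 ± 0.08 (adjusted p = 4.87e-08). Fat genes split into 28 higher and 30 lower of 84: acs-2 rose by 4.34 ± 0.34 while fat-7 (-5.49 ± 0.34), acdh-1 (-5.58 ± 0.91) and elo-6 (-3.96 ± 0.22, adjusted p = 7.27e-10) fell. The protease genes asp-13 and cpr-5 fell, at -5.90 ± 0.56 and -3.59 ± 0.22, within 20 higher and 34 lower of 78 autophagy and lysosome genes. Of 6 vitellogenins 4 fell and 6 did so adjusted over the list alone, while 2 of 38 oocyte genes fell and 0 adjusted over the list alone (8 fell without control 7, median -1.21 against -0.95).

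Of 87 sperm genes 33 rose and 0 fell (30 and 0 adjusted over the list alone; adjusted p = 0.894 with an estimated correlation). The share higher in this list is no larger than the 7397 of 17492 over all genes. Control 7 stands apart in this list too, at 0.95 against -0.55 and -0.40 in control 4 and 6 and 1.22 to 1.31 with 25 µM bortezomib. Cuticle collagens, a list in which control 7 stands apart, gave 72 higher and 3 lower of 148, with col-65 at 4.37 ± 1.01, and neuronal genes 50 higher and 0 lower of 55, with flp-34 at 4.39 ± 0.29 (76.5 ± 13.8 against 2.68 ± 0.46 FPKM) and flp-13 at 1.61 ± 0.22. cyp-35A2 fell (-4.63 ± 0.44), the glucuronosyltransferase gene ugt-22 fell (-4.12 ± 0.18), and cdr-4 rose by 2.39 ± 0.16. With 1 library left out, 7804 to 9883 genes were called.

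How does bortezomib at 25 µM differ from 10 µM? lys-3 was higher by 5.94 ± 0.24 (229.8 ± 10.7 against 2.79 ± 0.616 FPKM; adjusted p = 3.05e-11), the F-box genes fbxa-75 by 5.47 ± 0.16 and fbxa-126 by 4.81 ± 0.11, spp-20 by 5.22 ± 0.26 and pals-10 by 4.65 ± 0.20. acdh-2 differed by -5.62 ± 0.36 (2.37 ± 2.62 against 134.7 ± 3.34 FPKM; adjusted p = 8.89e-09), folt-2 by -5.44 ± 0.39, asp-13 by -5.39 ± 0.56, vit-3 by -5.38 ± 0.70 and fat-7 by -3.75 ± 0.34. Here 6932 genes were called, 4765 higher and 2167 lower at 25 µM (3742 and 3069 with median-of-ratios scaling, 2295 and 3550 with quantile normalization), 2976 at least 2-fold, with an all-gene median of 0.27.

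Of 34 subunits 3 were lower and 0 higher at 25 µM, and 0 and 0 adjusted over the list alone (median -0.14); rpn-6.1 differed by -0.01 ± 0.14, with a 95% interval from -0.29 to 0.28, and rpn-10 by 0.05 ± 0.09, from -0.15 to 0.25. The oxidative stress reporter gst-4 differed by -0.11 ± 0.16, with an interval from -0.45 to 0.22. Of 40 intracellular pathogen response genes 33 were higher and 0 lower (36 and 0 adjusted over the list alone; median 2.01; adjusted p = 0.0996 with an estimated correlation): pals-3 by 3.78 ± 0.20 (adjusted p = 8.51e-10), pals-29 by 3.67 ± 0.19 and cul-6 by 1.68 ± 0.20. Antimicrobial genes gave 39 higher and 18 lower of 92, with fipr-26 at 4.52 ± 0.71 and ilys-5 at -4.79 ± 0.46.

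hsp-60 differed by -1.39 ± 0.14 (adjusted p = 9.78e-07), the mitochondrial HSP70 gene hsp-6 by -0.56 ± 0.10 and atfs-1 by -0.63 ± 0.11; 7 of 11 mitochondrial stress genes were lower and 0 higher (adjusted p = 0.0996 with an estimated correlation), and 36 of 50 respiratory chain genes (0 and 38 adjusted over the list alone; adjusted p = 0.103 with an estimated correlation), with gas-1 at -0.79 ± 0.13 and atp-2 at -0.64 ± 0.08. Cuticle collagens, called in 1 gene at 10 µM, gave 85 higher and 1 lower of 148 at 25 against 10 µM (median 2.02; 89 and 1 adjusted over the list alone; adjusted p = 0.681 with an estimated correlation), such as col-65 (4.18 ± 1.01), col-113 (4.01 ± 0.83) and col-90 (3.87 ± 0.91). Neuronal genes gave 45 higher and 0 lower of 55, led by flp-34 at 3.46 ± 0.29 (adjusted p = 1.80e-07). Fasting and fat metabolism genes gave 14 higher and 30 lower of 84 (adjusted p = 0.0996 with an estimated correlation). No paired analysis was possible because the 2 doses share no replicate number, and leaving out 1 library gave 4980 to 5811 called genes.

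How does bortezomib at 25 µM differ from rpn-6 RNAi? The RNAi target differed, rpn-6.1 being higher with the drug by 0.83 ± 0.14 (216.6 ± 5.84 against 121.2 ± 6.16 FPKM; adjusted p = 5.52e-04), whereas 32 of the 34 proteasome subunits were not called, 2 were higher, rpn-6.1 among them, and 0 lower (median -0.11; 1 and 0 adjusted over the list alone). rpn-10, for one, differed by 0.00 ± 0.09, with a 95% interval from -0.20 to 0.20. Among heat shock genes, hsp-70 differed by -2.33 ± 0.35 (adjusted p = 2.54e-04), hsp-17 by -1.62 ± 0.32, hsp-16.41 by -1.48 ± 0.31 and hsp-16.2 by -1.30 ± 0.25 (153.9 ± 16.5 against 380.2 ± 18.6 FPKM). The list gave 0 higher and 19 lower of 31 (1 and 23 adjusted over the list alone; median -0.51; adjusted p = 0.0552 with an estimated correlation). Altogether 3861 genes were called, 2460 higher and 1401 lower with bortezomib (2151 and 1329 with median-of-ratios scaling, 1855 and 2379 with quantile normalization), 1903 at least 2-fold, with an all-gene median of 0.03. A fit of the 2 groups alone called 8403 genes. A replicate block called 448, 187 higher and 261 lower, and whether the replicate numbers pair these libraries is not known.

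Among named genes, the fungus-induced peptide gene fipr-26 was higher by 5.29 ± 0.71 and lys-3 by 3.06 ± 0.24 (adjusted p = 4.78e-07), within 25 higher and 14 lower of 92 antimicrobial genes, and cyp-34A2 by 2.31 ± 0.39. Lower were rpr-1, the RNA of RNase P (-5.14 ± 0.59), the chitinase-like genes chil-9 (-4.18 ± 0.18, adjusted p = 7.17e-10) and chil-18 (-3.68 ± 0.30), gst-24 (-3.88 ± 0.26), pgp-8 (-3.82 ± 0.17), cdr-4 (-1.92 ± 0.16) and fat-7 (-3.22 ± 0.34). Both numr-1 copies were lower, -2.31 ± 0.32 and -2.30 ± 0.32 at WBGene00017270 and WBGene00017267, uncertain as to copy. Intracellular pathogen response genes gave 2 higher and 20 lower of 40 (2 and 23 adjusted over the list alone; adjusted p = 0.238 with an estimated correlation), with pals-28 at -2.12 ± 0.14. ubq-1, a polyubiquitin gene, differed by -0.62 ± 0.13, the E1 enzyme gene uba-1 by -0.72 ± 0.13 and hsp-60 by -0.91 ± 0.14 (adjusted p = 2.81e-04); skn-1 was lower too (-0.48 ± 0.10). Sperm genes gave 19 higher and 0 lower of 87. Each of the 6 libraries matters to the count: 2185, 1913 and 2397 genes without RNAi 4, 5 and 6, and 2460, 1981 and 2145 without bortezomib 25 µM replicates 3, 4 and 6.

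**Figure D3:**
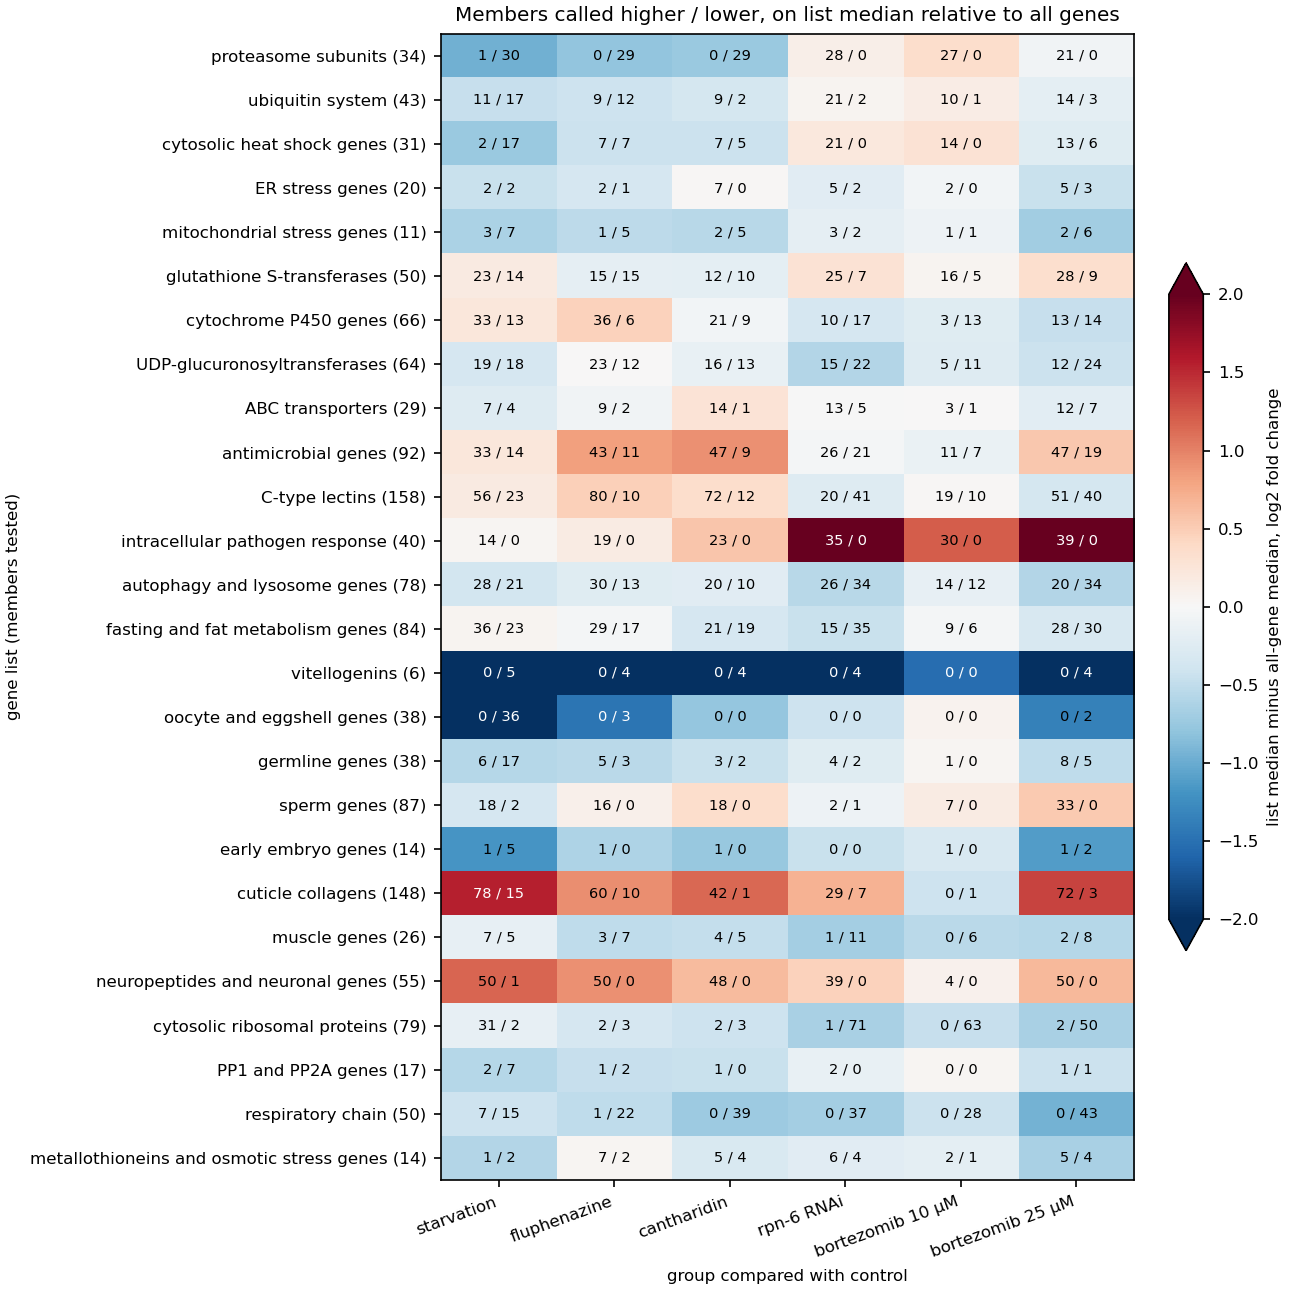
Members called higher / lower for the 26 gene lists (y axis, members tested in brackets) in each group against control (x axis, 3 libraries per group), on a colour scale of the list median minus the all-gene median in log2 units. Intracellular pathogen response genes go from 14 / 0 in starvation to 39 / 0 with 25 µM bortezomib, and proteasome subunits from 1 / 30 to 21 / 0.

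How far do the 6 treatments share genes? 607 genes were higher in all 6 and 143 lower in all 6, of 14481 called in any. The values for independent lists are 8.5 and 0, and 50 simulations of unchanged groups sharing simulated controls gave 0 and 0. Unchanged groups give almost no calls, so these simulated counts do not measure what shared controls add to the overlap. In the 3 proteasome treatments 1126 were higher and 404 lower, against 198.5 and 5.5 for independent lists and 0 and 0 simulated. These counts include the 607 and 143 genes shared by all 6, so they are not a set particular to the proteasome treatments. With median-of-ratios scaling the genes shared by all 6 were 234 higher and 588 lower, so the direction of this set turns with the scaling. The total was 822 with that scaling and 750 with the FPKM as deposited.

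The highest r between fold changes was that of starvation and fluphenazine, 0.85 (0.49 simulated), with a covariance of 0.948 (0.086 simulated), and 5170 genes higher in both (2353 for independent lists), 1426 lower in both (303) and 44 opposite; sqst-1, acs-2 and lipl-3 rose in both and vit-3 and fat-7 fell in both. The direct contrast of fluphenazine with starvation called 1101 genes. Fluphenazine and cantharidin had r = 0.8 (0.52), a covariance of 0.744 (0.091), 4367 genes higher in both (1921), 781 lower in both (98) and 36 opposite, with 1354 genes called between them. rpn-6 RNAi and 25 µM bortezomib had r = 0.75 (0.43), the highest covariance, 0.998 (0.076), 3926 higher in both (2065), 1147 lower in both (171) and 36 opposite; eol-1, pals-39 and hsp-16.2 rose in both. The 2 bortezomib doses had r = 0.66 (0.47) and a covariance of 0.558 (0.085), with 1485 higher in both (711) and 447 lower in both (63). rpn-6 RNAi and 10 µM bortezomib had r = 0.49 (0.46) and a covariance of 0.356 (0.082). Starvation and 10 µM bortezomib had the lowest r, 0.29 (0.47), a covariance of 0.22 (0.083) and 9768 genes called between them. Single simulations of unchanged groups reached r of 0.85 to 0.97, so no r lies above all of them. The covariance lies above its highest simulated value in 11 of 15 pairs and below it in 4, those of 10 µM bortezomib with starvation (0.358), fluphenazine (0.261), cantharidin (0.338) and rpn-6 RNAi (0.373). The 3 control libraries were too few to split, so the part of each excess that comes from the shared controls was not measured. The genes shared by all 6 numbered 472, 562 and 906 without control 4, 6 and 7.

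**Figure D4:**
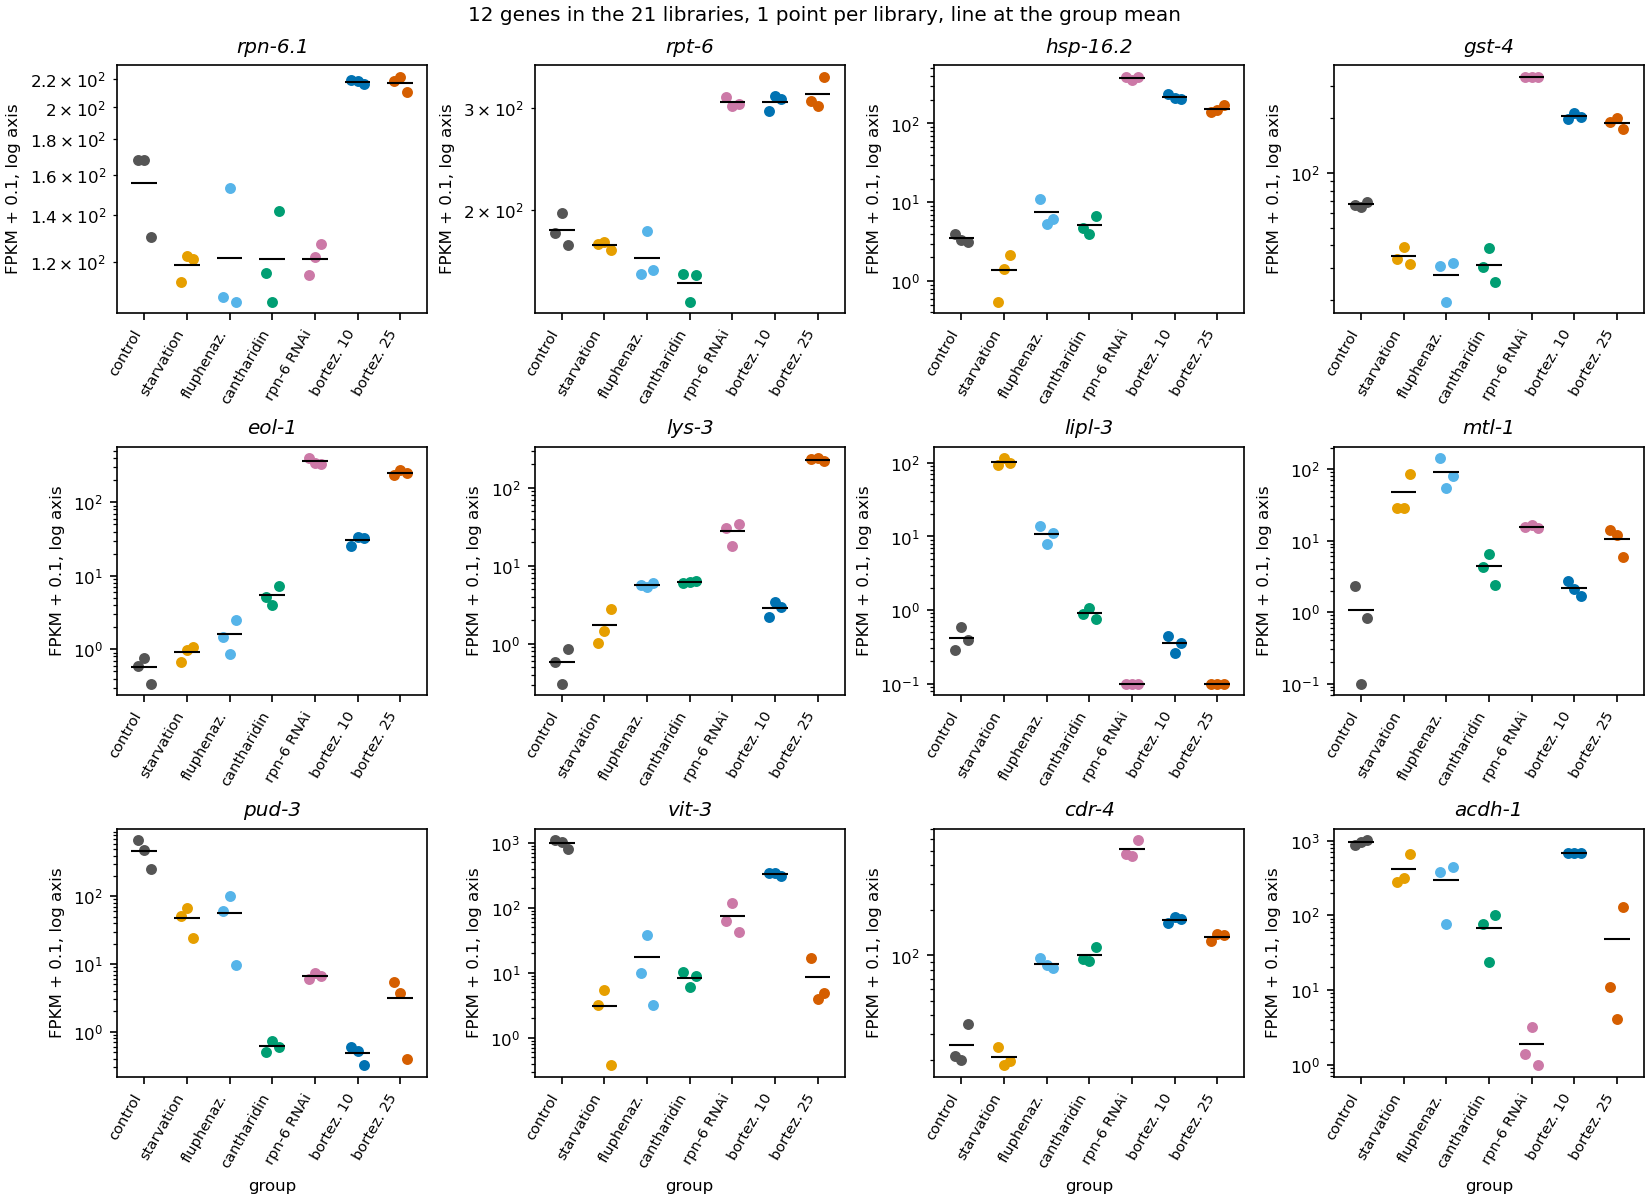
FPKM plus 0.1 on a log axis (y) for 12 genes in the 7 groups (x), 1 point per library and a line at the group mean of 3. eol-1 stands at 0.242 to 0.661 FPKM in control and 335 to 396.9 in rpn-6 RNAi, and lys-3 at 218.3 to 239.4 in 25 µM bortezomib.

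**Figure D5:**
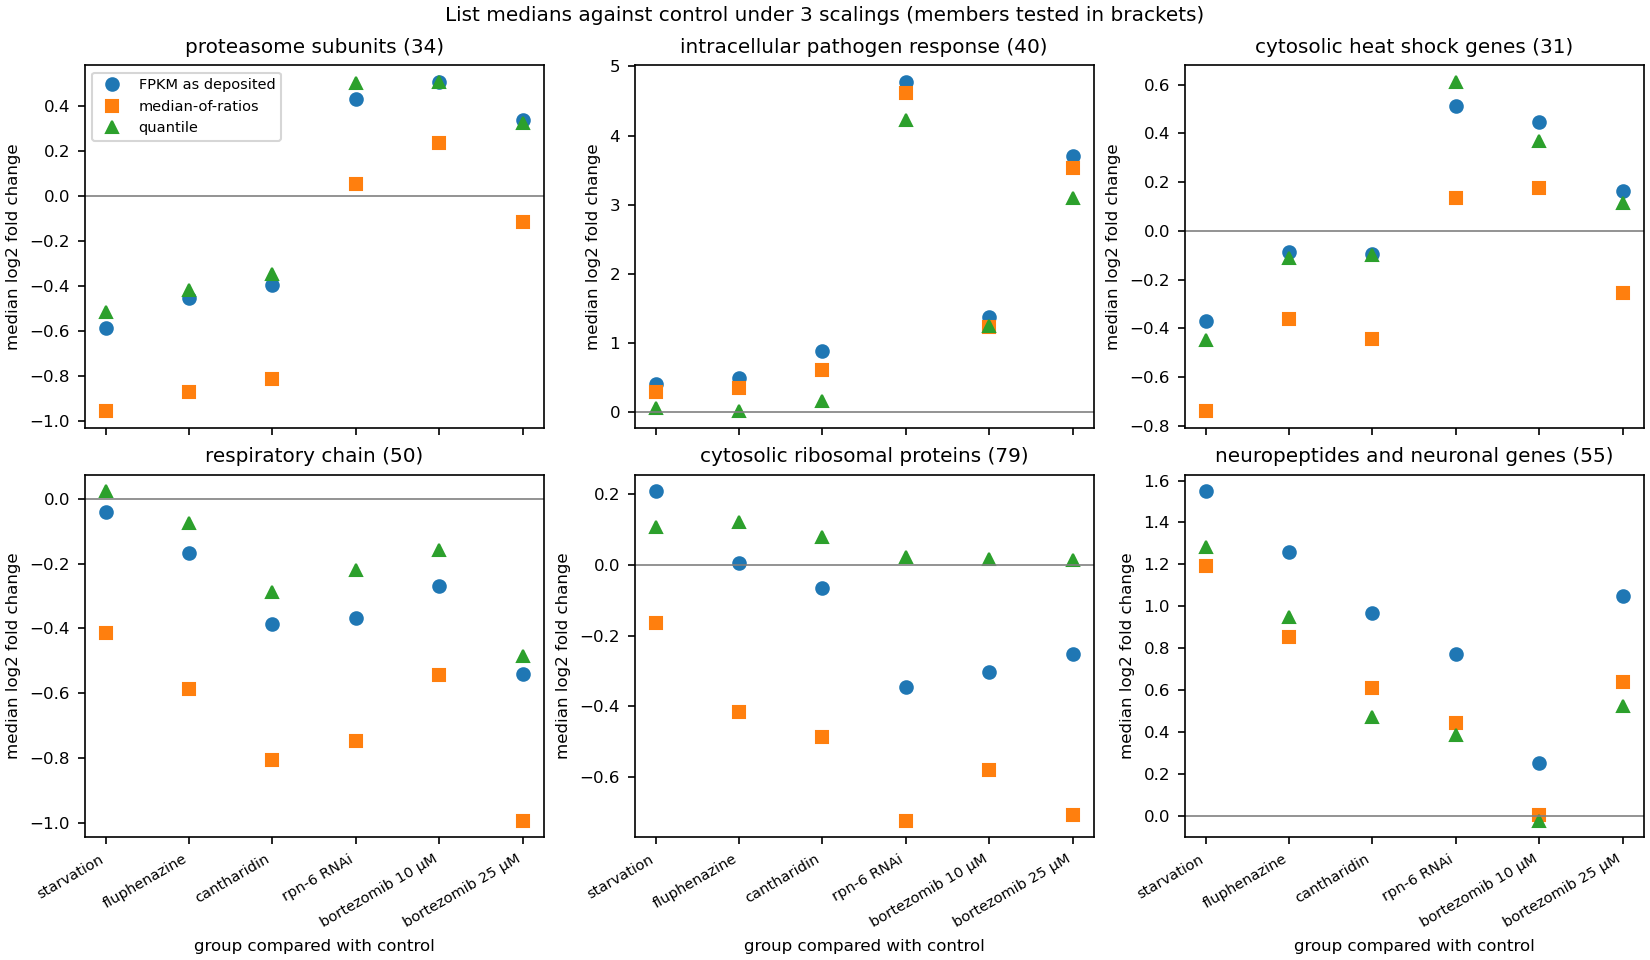
Median log2 fold change against control (y axis) of 6 gene lists in the 6 treated groups (x axis), with 1 point for each of 3 scalings. For proteasome subunits in 25 µM bortezomib the points lie at 0.34 with the FPKM as deposited, -0.11 with median-of-ratios scaling and 0.32 with quantile normalization.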

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

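The alternatives fixed before the data were examined changed processing 1 choice at a time; the fits without the 3 libraries that stand apart (control 7, fluphenazine 4 and starvation 3) and with zeros of abundant genes as missing were added afterwards. Among the called results of genes named in the text, 269 were followed through the settings: 244 kept their call and direction in every setting, 25 lost it in at least 1 and 0 reversed. Since genes were named mainly where the call held with each library left out, this share says little about other genes. Counts stayed within 1.5 times under the other pseudocount, both other filters, both other scalings and with zeros as missing, while the balance of higher and lower calls turned with the scaling. Array weights raised the counts of called genes to 15185 for starvation, 15329 for fluphenazine, 13749 for cantharidin, 12247 for rpn-6 RNAi, 8467 and 14141 for 10 and 25 µM bortezomib, 13588 for the 2 doses, 10974 for bortezomib against RNAi and 204031 summed over the 15 pairs of treatments (77201 without weights); the weight estimation stopped before convergence, so these counts carry little. Without the 3 libraries the counts were 13249 for fluphenazine, 11411 for cantharidin, 10082 for rpn-6 RNAi, 5360 for 10 µM bortezomib, 11937 for the 2 doses, 9171 for bortezomib against RNAi, 141956 summed over the pairs, and 3168 for genes shared by all 6 treatments (750 with all libraries). Fits of only the 2 groups, with fewer degrees of freedom, called 5398 genes for starvation, 2567 for fluphenazine, 12085 for the 2 doses and 8403 for bortezomib against RNAi. For the 2 doses and for bortezomib against RNAi, leaving out the 3 libraries cannot alter the fold changes, since none belongs to those groups. Their all-gene medians stayed at 0.27 and 0.03 without the 3 libraries and in fits of the 2 groups. In these 2 comparisons the pooled spread therefore held the counts down with all libraries. For the other comparisons the cause was not tested.

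With 1 library left out the counts ran from 7518 to 11020 for starvation, 4560 to 11010 for fluphenazine, 4319 to 7739 for cantharidin, 5216 to 6073 for rpn-6 RNAi, 1124 to 2514 and 7804 to 9883 for the bortezomib doses, 4980 to 5811 between the doses, 1913 to 2460 for bortezomib against RNAi and 66752 to 98377 summed over the pairs; with 1 control left out, genes shared by all 6 ran from 472 to 906. Of 208 list tests 4 were called (1.92%), 0% to 2.88% with 1 library left out (0% without control 7), 4.81% with no filter, 0.962% with the filter at 5 FPKM, 0% with array weights, without the 3 libraries or in fits of only the 2 groups, 57.2% with a preset correlation of 0.01 and 46.2% with fry. The last 2 ask other questions: a preset correlation ignores how strongly members of these lists vary together, and fry tests whether members change in a common direction, whatever the other genes do. No list call held in every setting: adjusted p ran from 0.0308 to 0.538 for respiratory chain genes in cantharidin and from 0.0231 to 0.385 in rpn-6 RNAi, where pathogen response genes had 0.00219 to 0.17 and fat genes 0.014 to 0.178.

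A replicate block was fitted for the 3 comparisons whose groups share the numbers 4 and 6. It gave 4016 called genes for rpn-6 RNAi, 6877 for 25 µM bortezomib and 448 for bortezomib against RNAi (187 higher and 261 lower, against 2460 and 1401 without it), and the 3 list calls of these comparisons were lost, which leaves 1 of the 208 list tests (0.481%), a call of a comparison without a block. Deviations of libraries with the same number correlated at -0.16, 0.05, -0.13, -0.26, -0.11 and -0.05, and those with different numbers at -0.28 to 0.17. Control 4 and 6 correlated nearly alike with each of these libraries, for example at 0.05 and 0.06 with bortezomib 25 µM replicate 4. Values with a control therefore cannot show pairing. Between RNAi and bortezomib the same number gave -0.11 and -0.05 and different numbers 0.17 and 0.09, too few values to decide.

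Depth differed by 1.59-fold at most. With 3 libraries per group, a gene changed 1.5-fold was recovered in 16% to 30% of simulated cases. The simulations changed far fewer genes than the real comparisons called, so their adjusted cutoff was stricter. These rates are therefore not the power of the real comparisons. A gene that was not called may still differ 1.5-fold.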

Other observations

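The families of genes in this part, and the tests of exchanged labels, of depth, of the germline share, of abundant genes and of scaling, were chosen after the results were seen; the tests on molting genes and adult collagens and the splits were written before. Outside the 26 lists, 71 families of genes that share a symbol prefix had at least 15 tested members. Camera with an estimated correlation called 0 of 568 family tests (171 with a preset correlation of 0.01), so the counts describe members only. Mitochondrial ribosomal protein genes of the large subunit (mrpl, 40 genes) were lower in 24 and higher in 3 with starvation, 24 and 1 with fluphenazine, 19 and 0 with cantharidin and 24 and 1 with 25 µM bortezomib, but 3 and 3 with 10 µM. The count for rpn-6 RNAi is not given here. In that group mrpl-12 (-0.66 ± 0.08) and mrpl-24 (-0.53 ± 0.09) fell, while mrpl-20 (-0.28 ± 0.14) and mrpl-19 (-0.22 ± 0.11) were not called. mrpl-24 changed by -0.91 ± 0.09 in starvation and mrpl-12 by -1.04 ± 0.08 with 25 µM bortezomib (adjusted p = 2.53e-08). Small-subunit genes (mrps, 25) gave 15 lower and 3 higher in starvation and 18 and 2 with 25 µM bortezomib; mrps-15 changed by -0.67 ± 0.07 and mrps-11 by 0.69 ± 0.06 with that dose. Nuclear pore genes (npp, 25) were lower in 15 and higher in 0 with starvation, npp-23 at -1.06 ± 0.20.

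Neuropeptide-like genes (nlp, 62) were higher in 53 and lower in 0 with starvation and in 54 and 1 with 25 µM bortezomib. nlp-62 rose in both (2.38 ± 0.28 and 3.60 ± 0.28), as did nlp-2 (2.93 ± 0.22 and 1.78 ± 0.22). nlp-39 rose by 4.47 ± 0.35 with 25 µM bortezomib (adjusted p = 3.16e-08) and was not called in starvation (0.19 ± 0.35), and differed between the 2 by 4.28 ± 0.35 (adjusted p = 7.23e-08). F-box genes of the fbxa family (139) were higher in 102 and lower in 3 with 25 µM bortezomib, 85 and 4 with rpn-6 RNAi and 47 and 0 with 10 µM. fbxa-158 rose by 5.88 ± 0.32 with 25 µM bortezomib and 6.06 ± 0.32 with RNAi. It also rose with cantharidin (3.66 ± 0.32), fluphenazine (2.05 ± 0.32) and starvation (1.96 ± 0.32), where fbxa-116 was not called. The nspc genes (18), nematode-specific peptides, were lower in 17 and higher in 0 with 25 µM bortezomib against control (median -1.42) and the same against RNAi (-1.43), with nspc-13 at -2.61 ± 0.23 (adjusted p = 1.27e-07) against control, whereas in starvation 11 were higher and 0 lower (nspc-13 1.74 ± 0.23). Falls were not limited to that dose: nspc-5 fell with fluphenazine (-1.59 ± 0.26), cantharidin (-1.55 ± 0.26) and 10 µM bortezomib (-1.14 ± 0.26). nspc-9 was not called with fluphenazine or 10 µM bortezomib.

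The first pattern is that control 7 and fluphenazine 4 stand apart from their groups. An exchange of their labels is argued against: over 48 genes that mark fluphenazine 2 and 9, fluphenazine 4 had a median position of 0.874 between control (0) and fluphenazine (1), with quartiles 0.687 and 0.951, and control 7 stood at 0.013. Lower depth is argued against too, since the 3 other libraries no deeper than control 7 had a median correlation of 0.962 with their groups (0.961 to 0.976; control 7 0.938, fluphenazine 4 0.891). Over 49 molting genes, fluphenazine 4 lay below fluphenazine 2 and 9 by a median of -1.97 (quartiles -3.27 and -1.08; 45 lower), which goes with collection farther from the last molt, as predicted beforehand, and stays a hypothesis. Control 7 lay above control 4 and 6 by a median of 0.47 (quartiles 0.13 and 1.09; 42 higher), under the bound of 0.5 written beforehand but not by more than the spread of its members, a criterion set after the values were seen, so collection closer to the molt stays open.

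The next pattern is starvation 3, apart from starvation 1 and 2. Low depth is argued against by its relative depth of 1.108, between 1.049 and 1.165 in the other 2. Younger animals were expected to have lower adult collagens. The median of 5 collagens taken as adult was 2.15 with quartiles -1.4 and 2.18, and starvation 1 and 2 differed from each other by 1.86. The 5 moved apart in starvation 3: col-38, col-49 and col-63 were higher, and col-7 and col-62 lower. Whether all 5 mark the adult stage was not tested, so their median cannot decide. The bound written beforehand (above -0.5) was met by the median but not by the spread, by the same later criterion, so age stays open. No other biological explanation was tested.

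The remaining pattern is the larger share of higher calls in every treatment (68% to 84.3%). A lower share of germline RNA alone was predicted to raise neuronal and muscle genes alike. Neuronal minus muscle level was at least 0.546 in the 18 treated libraries and at most 0.117 in the controls. Yet control 7, with oocyte genes at -0.53, was at 0.42 in muscle and 0.19 in neuronal genes, so the 2 lists need not move alike. The test therefore cannot decide on the germline share. For a few abundant genes losing their share, the top 10 held at most 3.6% of the FPKM sum in a control. FPKM is divided by transcript length, and the share of mapped fragments, on which this explanation rests, was not computed. The value therefore argues only against a large share of the FPKM sum, and the explanation stays open. Scaling cannot be told apart from a true shift: median-of-ratios scaling brought the share to between 38.4% and 52.7%, but centring fixes that outcome.

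Each comparison of 3 with 3 libraries allows 10 splits, too few splits for a share under 0.05. The real split called most genes in 7 comparisons, so that 1 split was as large: 10066 against 2341 for the highest other in starvation, 6628 against 2 in cantharidin, 6425 against 3 in rpn-6 RNAi, 2248 against 0 and 9333 against 3 in the bortezomib doses, 6932 against 1 between doses and 3861 against 2 for bortezomib against RNAi. In fluphenazine 2 splits were as large: the real one called 7658 genes, and grouping control 4 and 6 with fluphenazine 4 called 8658.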
